A study of Homo sapiens with 8 samples.

How the data were processed

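RNA of H1299 cells was measured on 8 Affymetrix PrimeView arrays, with biotin-labelled total RNA and 1 colour per array, per the labels. The labels gave 4 groups: USF1 control and USF1 knockdown with 3 arrays each, and UGT1A3 control and UGT1A3 knockdown with 1 array each. The authors deposited 1 table of log2 intensities per probe set, and the log base was read from the range of the values. MAS5 is named per the submitters' processing notes, without a role or a version, and the method by which the authors scaled the arrays to each other is not given in the sources used here. The deposited log2 medians of the UGT1A3 arrays lay about 1 unit below those of the USF1 arrays, so no gene was tested across the 2 sets, and only differences formed within a set were set side by side. Pearson's correlation over probe sets was 0.998 to 0.999 within the USF1 groups, 0.996 to 0.997 between them, 0.995 in the UGT1A3 pair and 0.978 to 0.98 between the sets.

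The table held 49395 probe sets, of which 102 were control probe sets and were left out of all tests. Gene names came from the platform annotation, with 44988 probe sets carrying 1 gene symbol, 1832 several and 2473 none. Symbols were looked up by Entrez number in a gene table of assembly GRCh38.p14, where 44961 matched, and no coordinates were used. Probe sets with several symbols named no gene. The 1 exception was the UGT1A locus, whose 9 probe sets were reported as shared, outside all counts. Each of 18132 genes was represented by its probe set of highest mean over the arrays of the comparison, and for many named genes whose bright probe sets disagreed the range over those probe sets was given. Genes under the 40th percentile of probe set means, at log2 5.63 in the USF1 arrays and 4.76 in the UGT1A3 arrays, were left out as dim. This left 11448 genes for the USF1 comparison and 11620 for the UGT1A3 comparison. The limit applied to the mean over the arrays of a set, so 1 group of a kept gene could lie under it. For several named genes of this kind the difference was also counted from the limit.

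The USF1 comparison was fitted on the deposited log2 values with limma 3.58.1 (lmFit and eBayes, R 4.3.3), without a replicate block. P-values were two-sided, adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. Changes are knockdown minus control on the log2 scale. SE is the moderated standard error, and the median within-group SD over genes was 0.05. For the UGT1A3 pair only differences were computed.

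The 29 gene lists, with 789 members of which 704 had a named probe set, covered neurotrophin signalling, the UGT family, E-box factors, reported USF targets, lysosome, cell cycle phases, histones, p53 targets, apoptosis, lipid and energy metabolism, stress responses, interferon and inflammatory responses, ERK feedback, TGF-beta targets, epithelial and mesenchymal genes, ribosomal proteins and markers of other cell types. They were tested against all other genes with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the arrays. Adjustment was over the 25 lists with at least 5 measured members. In the UGT1A3 pair, and for the genes that passed after USF1 knockdown, a list's median was set among 10000 and 2000 random lists, respectively, of the same size matched on mean expression in 20 bins.

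The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Departing from that plan, the genes that passed after USF1 knockdown were set among 2000 random lists in place of 10000. By that rule the text names the targeted genes and measured UGT genes, and the 10 largest rises and 10 largest falls after USF1 knockdown among genes past the threshold whose knockdown arrays all lay on one side of the controls. It also names up to 4 members per list with the smallest adjusted p, or 2 with the largest change where none passed. For the UGT1A3 pair it takes the 8 largest differences in each direction and up to 2 members per list, and for both sets up to 10 genes that passed and were at least 2-fold the same way. Of the genes the rule takes, some list members were left out of the text.

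The alternatives were quantile normalization, centring each array on its median, no dim limit, a dim limit at the 60th percentile, 16 intensity units added before log2, the mean of all probe sets of a gene, every probe set tested on its own, an intensity trend with a robust prior in eBayes, the replicate number as a block, and leaving out each USF1 array in turn. The fit was tested on simulated data for the USF1 comparison, with 11448 genes of which 200 were changed, 50 at each fold. It called 1 of 50 genes changed by 1.1-fold, 47 of 50 at 1.25-fold and all 50 at 1.5-fold and at 2-fold, with 7 false calls among 155. A planted list was called and 0 others were. The genes were simulated independently of each other, so this does not test the list calls where genes of a list vary together. Far fewer genes were changed than the 4657 of 11448 that passed in the arrays, so an adjusted p of 0.05 was harder to reach. The shares called at each fold are therefore not detection limits of the real comparison, where ASPH passed at 1.06-fold.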

Results

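Gene expression was profiled in H1299, an established human non-small cell lung carcinoma cell line, on 8 one-colour Affymetrix arrays. In the first set, cells transfected with short hairpin RNA against USF1 were compared with their controls, with 3 arrays in each group. USF1 is a basic helix-loop-helix leucine zipper transcription factor that binds E-box sequences. In the second set, 1 array of cells transfected with short hairpin RNA against UGT1A3 was compared with 1 control array. UGT1A3 is a UDP-glucuronosyltransferase that conjugates glucuronic acid to lipophilic compounds. The title of the study links USF1 to UGT1A3 and to neurotrophin signalling, so the targeted genes and the neurotrophin genes were examined in both sets. The median log2 intensity was between 6.53 and 6.55 on the 6 USF1 arrays and was 5.59 and 5.63 on the UGT1A3 control and knockdown arrays, so each knockdown was compared only with the controls of its own set. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

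USF1 fell by 0.40 on the log2 scale after USF1 knockdown (SE 0.08, n = 3 against 3, limma adjusted p = 0.00818), to 75.6% of the control level. The single USF1 probe set read 6.31, 6.55 and 6.42 in the controls and 6.06, 5.88 and 6.13 in the knockdown arrays. In the UGT1A3 pair USF1 read 4.73 in the control, under the dim limit of 4.76, and 4.98 in the knockdown array, a difference of 0.25 with no replicate check. USF2, the closest relative of USF1, differed by -0.02 (SE 0.03, adjusted p = 0.655), and its 5 bright probe sets gave differences of -0.03 to 0.03. UGT1A3 had no probe set of its own. Its 9 probe sets were shared with other genes of the UGT1A locus, 8 of them with all 9 UGT1A genes, and each lay under the limit for dim probe sets in both sets of arrays. The brightest shared UGT1A probe set had a mean of 5.03 in the USF1 controls and 4.94 after USF1 knockdown, a difference of -0.09 (SE 0.10, adjusted p = 0.595 with no filter on dim probe sets). This difference was -0.14 and -0.06 without USF1 control 1 and 2, and -0.04, -0.04 and -0.20 without USF1 knockdown 1, 2 and 3. Over the 9 shared probe sets the differences ran from -0.15 to 0.21, and when all probe sets were tested singly 1 of the 9 passed, upward, on a mean of 3.04 (0.21, SE 0.05, adjusted p = 0.039). In the UGT1A3 pair the brightest shared UGT1A probe set read 4.56 in the control and 4.31 in the knockdown array, a difference of -0.25 with no replicate check. Over the 9 shared probe sets the differences in this pair ran from -0.45 to 0.06. These values therefore concern the UGT1A genes jointly, at intensities near background. UGT8, a galactosyltransferase of the same superfamily and the only UGT gene bright enough to be tested in the USF1 arrays, differed by -0.04 (SE 0.03, adjusted p = 0.437). Its 3 bright probe sets gave -0.29 to -0.03, and the mean of all its probe sets gave -0.12 (adjusted p = 0.0406).

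**Figure D1:**
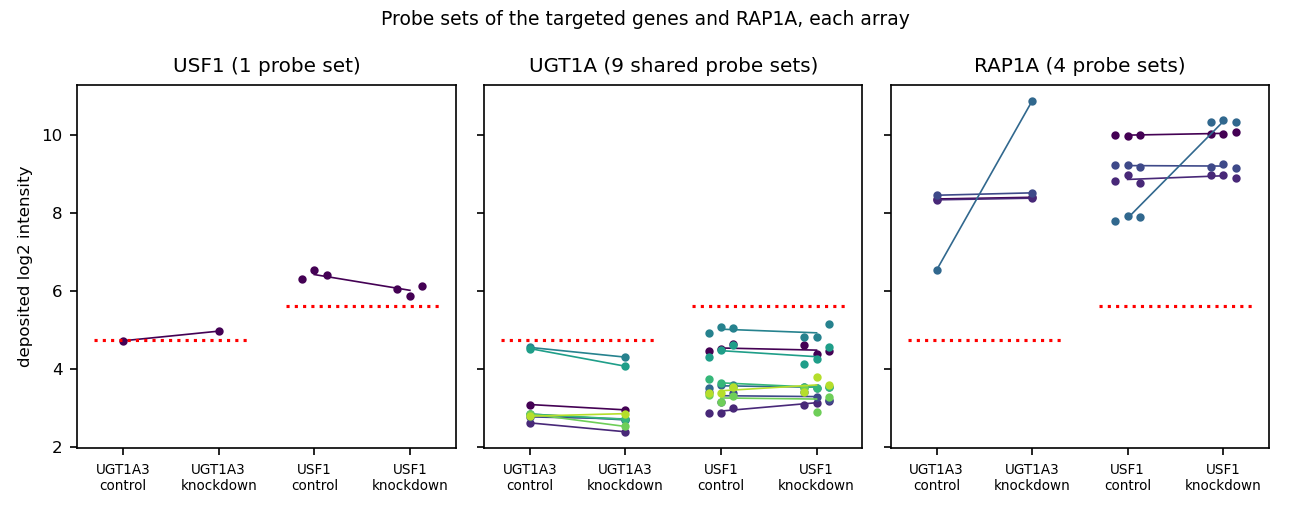
Deposited log2 intensity (vertical axis) of each probe set of USF1, of the UGT1A genes and of RAP1A on each array (points), grouped by condition, with lines joining the group means within each set of arrays and dotted lines at the limits for dim probe sets, 4.76 for the UGT1A3 arrays and 5.63 for the USF1 arrays. The USF1 probe set was lower in the 3 USF1 knockdown arrays than in the 3 controls, the shared UGT1A probe sets all had means under the limits, and 1 of the 4 RAP1A probe sets was higher by 2.48 after USF1 knockdown and by 4.34 in the UGT1A3 pair.

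After USF1 knockdown the largest rises were in BFSP1, a beaded filament protein known from the lens (1.44, SE 0.08, n = 3 against 3), and S100A4, a calcium-binding protein tied to cell motility (1.28, SE 0.06). ID2, an inhibitor of basic helix-loop-helix factors, rose by 1.22 (SE 0.06) and the cholesterol exporter ABCA1 by 1.01. PLSCR4 rose from a control mean of 5.59, under the dim limit of 5.63, to 6.72, by 1.14 as measured and 1.09 counted from the limit. The metalloproteinase inhibitor RECK rose by 0.97, the gamma-secretase subunit APH1B by 0.95, and TP53INP1, MAP2 and CD82 by 0.84 to 0.86. With the mean of all probe sets ABCA1 rose by 0.59 and TP53INP1 by 0.46. The largest falls were in NCEH1, a neutral cholesterol ester hydrolase (-1.80, SE 0.06), the interstitial collagenase MMP1 (-1.70, SE 0.04), the oligopeptidase THOP1 (-1.69, SE 0.04) and the signal recognition particle subunit SRP9 (-1.61, SE 0.03). CPD fell by 1.58, PTS by 1.27, IMP4 by 1.24, HADH by 1.22 and RPE by 1.20. TMEM182 fell from 6.91 to a mean of 5.58 under the limit, by 1.33 as measured and 1.28 counted from the limit, and its second bright probe set gave -0.55. By the rule that picked them, each of these 20 genes passed the threshold with its 3 knockdown arrays on one side of the 3 controls. Their limma adjusted p-values ran from 2.02e-06 for SRP9 to 5.82e-04 for MAP2.

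In all, 4657 of 11448 genes passed an adjusted p of 0.05, of which 2515 rose and 2142 fell. Most of these changes were small: 194 genes changed by at least 1.5-fold, 58 upward and 136 downward, and 27 by at least 2-fold, 5 upward and 22 downward. The median change over all tested genes was 0.01. Probe sets of some named genes disagreed in size. The bright probe sets of CPD gave changes from -1.58 to -0.16, those of RECK from 0.10 to 0.97 and those of APH1B from 0.56 to 0.95. The ranges were -0.61 to -0.02 for MCL1, -0.48 to -0.05 for ATF3 and 0.02 to 0.58 for SQSTM1, members of 3 of the fixed lists. The 2 bright probe sets of HADH gave -1.22 and -0.11, and without USF1 control 1 or control 2 the dimmer fall took its place (-0.11 and -0.08, adjusted p = 0.102 and 0.117), as it did without control 3 (-0.14, adjusted p = 0.0341).

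The list of unfolded protein response and ATF4 target genes, which serve amino acid supply and the response to protein stress, moved down after USF1 knockdown. Of its 33 measured members 18 fell and 5 rose, and adjusted over the list alone 19 fell and 6 rose. The cystine transporter subunit SLC7A11 fell by 1.13, the amino acid transporter SLC7A5 by 1.07, asparagine synthetase (ASNS) by 0.91 and the serine synthesis enzyme PSAT1 by 0.68, while the bright probe sets ran from -1.18 to -0.59 for SLC7A11 and from -1.07 to -0.44 for SLC7A5. The list median was -0.25 and its camera adjusted p was 8.59e-04 (adjusted p = 0.523 with an estimated correlation). Genes of the immediate early response and ERK feedback also moved down, with 11 falling and 5 rising of 29, the same counts adjusted over the list alone. EGR1 fell by 0.82, ATF3 by 0.48 and MYC by 0.37, whereas the bright probe sets of EGR1 ran from -0.95 to -0.37 and the 4 of PHLDA1 from -0.54 to 0.29. Its median was -0.07 with an adjusted p of 0.0307 (adjusted p = 0.595 with an estimated correlation, and a median of -0.04 with 0.0511 without USF1 control 2).

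Genes of the type I interferon response moved up: 11 of 19 rose and none fell, the same counts adjusted over the list alone. The antiviral effectors IFIT1 and IFIT3 rose by 0.57 and 0.45, the interferon signalling factor IRF9 by 0.52 (0.27 to 0.58 over its bright probe sets) and SAMD9 by 0.39. The median was 0.19 and the adjusted p was 0.00132 (adjusted p = 0.523 with an estimated correlation). Among TGF-beta targets 11 of 19 rose and 3 fell, and adjusted over the list alone 11 rose and 4 fell. ID2 and its relative ID3 rose by 1.22 and 0.70 and the receptor TGFBR2 by 0.46, while the bright probe sets of TPM1 ran from -0.15 to 0.41. The median of the TGF-beta targets was 0.24 with an adjusted p of 0.0307 (adjusted p = 0.595 with an estimated correlation). Of 30 lysosomal genes 17 rose and 4 fell, and adjusted over the list alone 18 rose and 4 fell. GABARAPL1 and SQSTM1, which act in autophagy, rose by 0.58 and 0.40, whereas LAMP1, an abundant lysosomal membrane protein, fell by 0.80, with bright probe sets from -0.80 to -0.35. The lysosomal median was 0.12 with an adjusted p of 0.0307 (adjusted p = 0.595 with an estimated correlation). The lysosomal call was lost without USF1 control 1 (0.0524) or USF1 knockdown 2 (0.0734), and with the dim limit at the 60th percentile the adjusted p was 0.0717 for the lysosomal and the immediate early lists and 0.071 for the TGF-beta targets. No list passed with an estimated correlation.

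The neurotrophin signalling list did not pass as a whole. Of its 76 measured members 27 rose, 14 fell and 35 did not pass, and adjusted over the list alone 30 rose and 14 fell. The kinases RPS6KA1 and MAP3K3 rose by 0.34 and 0.31 (0.14 to 0.31 over the bright MAP3K3 probe sets), whereas AKT2 fell by 0.32 (-0.43 to -0.15) and the transcription factor ATF4 by 0.29. The median was 0.06 and the camera adjusted p was 0.265 (adjusted p = 0.595 with an estimated correlation). With each gene taken as the mean of all its probe sets the median was 0.08 and the adjusted p 0.0343 (adjusted p = 0.758 with an estimated correlation). With RAP1A also left out of the list, an alternative chosen after seeing the data, the median stayed at 0.08 and the adjusted p was 0.0569. Of 13 measured genes reported as USF targets 3 rose and 1 fell (3 and 0 adjusted over the list alone), among them ABCA1 (1.01), the lipid carrier APOE (0.60) and the haem-degrading enzyme HMOX1 (0.25, or 0.16 to 0.30 over its bright probe sets), with an adjusted p of 0.377. Among 20 E-box factors 3 rose and 7 fell (3 and 8 adjusted over the list alone), with an adjusted p of 0.304. The bright probe sets of SREBF1 ran from -0.04 to 0.51 and those of MXD4 from -0.40 to 0.51.

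Cholesterol synthesis genes held 9 members that rose and 2 that fell of 19, the same adjusted over the list alone, with FDPS at 0.29, LSS at 0.26 and INSIG1 at -0.18. Their adjusted p was 0.0772, and it was 0.0349 with no filter on dim probe sets and 0.0343 with the mean of all probe sets (adjusted p = 0.523, 0.331 and 0.686 in turn with an estimated correlation). In fatty acid and lipid synthesis 8 of 22 rose and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.533), where the elongase ELOVL1 fell by 1.15 and the desaturase FADS1 rose by 0.52. Of 29 glycolysis and hypoxia genes 3 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.304), including falls of DDIT4 by 0.88, HK2 by 0.67 and VEGFA by 0.51, although the bright VEGFA probe sets ran from -0.64 to -0.03. In oxidative phosphorylation 2 of 25 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.477), with UQCRC2 at -0.16 and CYC1 at -0.16.

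Of 22 p53 targets 10 rose and 4 fell, the same adjusted over the list alone, with an adjusted p of 0.304. SESN1 rose by 0.60 and TP53INP1 by 0.86, whereas SESN2 fell by 0.59 and GADD45A by 0.24. Among apoptosis regulators 10 of 30 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.417), with BAD and BAK1 at 0.22 each and the survival factor MCL1 at -0.45. Of 10 replication-dependent histone genes 6 rose and 2 fell (7 and 2 adjusted over the list alone), with H2BC5 at 0.55 and H2BC21 at -0.44. The histone median was 0.21 and the adjusted p was 0.135, or 0.0454 without USF1 knockdown 3 (adjusted p = 0.595 and 0.512 in turn with an estimated correlation). In the G1/S and DNA replication list 6 of 34 rose and 6 fell (5 and 6 adjusted over the list alone), with the helicase subunit MCM6 at 0.25 (0.12 to 0.25 over its bright probe sets) and CCNE1 at -0.27 (-0.14 with the mean of all its probe sets). Its median and mean, 0.01 and 0.004, lay above 0 while the camera direction was down (adjusted p = 0.93). In the G2/M list 6 of 34 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.93), with CDC25B at 0.26 and the mitotic kinesin KIF11 at -0.32.

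Heat shock genes included 6 that rose and 2 that fell of 15, the same adjusted over the list alone (adjusted p = 0.32), with HSPB1 at 0.43 and HSPA1B at 0.37. In the NRF2 and xenobiotic list 8 of 24 rose and 4 fell (9 and 4 adjusted over the list alone, adjusted p = 0.4), led by the cytochromes CYP1A1 at 0.84, with bright probe sets from 0.44 to 0.84, and CYP1B1 at 0.68. Of 15 NF-kB and inflammatory genes 1 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.417). LIF fell by 0.67 and CXCL2 by 0.49, and BCL3 rose by 0.32. Among mesenchymal and matrix genes 8 of 23 rose and 5 fell (9 and 5 adjusted over the list alone, adjusted p = 0.304), with the collagen cross-linking enzyme LOXL2 at 0.45 and the transcription factor TWIST1 at -0.87. Of 12 epithelial genes 3 rose and none fell, the same adjusted over the list alone, namely PKP3 (0.30), KRT8 (0.25) and DSG2 (0.19). The epithelial median was -0.03, while the mean was 0.02 and the camera direction up (adjusted p = 0.84). Of 28 ribosomal protein genes 1 rose and 1 fell (0 and 1 adjusted over the list alone, adjusted p = 0.738), with RPS6 at -0.16.

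Markers of other cell types were mostly too dim to be tested. PDGFRB of fibroblasts differed by 0.04 (adjusted p = 0.71) and CD68 of leukocytes by -0.09 (adjusted p = 0.159, or -0.13 and 0.0242 without USF1 knockdown 2). Of the endothelial markers VWF differed by -0.01 and PECAM1 by less than 0.01 in size. None of 6 alveolar and airway markers passed, with or without adjustment over the list alone, and AGER and SFTPC differed by 0.09 and -0.07. Without USF1 knockdown 3 the SFTPC difference was -0.18 (adjusted p = 0.0129). The alveolar median was -0.001, while the mean was 0.002 and the camera direction down (adjusted p = 0.933). Of 8 neuronal and neuroendocrine markers 2 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.805), namely SYT1 (0.30, or 0.18 to 0.30 over its bright probe sets), ENO2 (0.15) and SNAP25 (-0.39). The lists of fibroblast, leukocyte, endothelial and UGT genes had fewer than 5 measured members and were not tested as lists. The difference between 3' and 5' control probe sets of GAPDH and ACTB averaged 0.28 in the controls and 0.27 in the knockdown arrays.

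**Figure D2:**
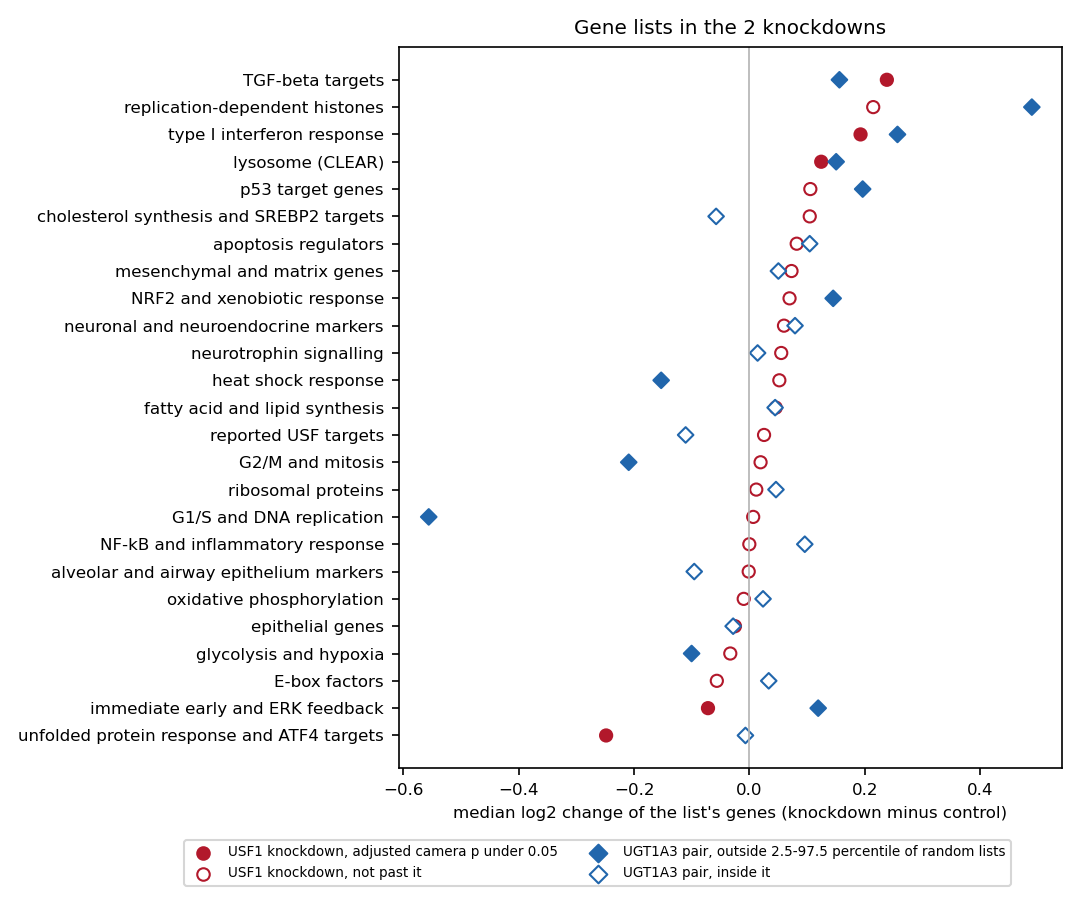
Median log2 change of the measured genes of each of the 25 tested lists (horizontal axis), after USF1 knockdown (circles, 3 against 3 arrays, filled where the camera adjusted p was under 0.05) and in the UGT1A3 pair (diamonds, 1 against 1 array, filled where the median lay outside the central 95% of random lists). Unfolded protein response and ATF4 targets had the lowest median after USF1 knockdown, at -0.25, and G1/S genes had the lowest in the UGT1A3 pair, at -0.56.

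In the UGT1A3 pair 20 of 11620 genes were at least 2-fold higher and 11 at least 2-fold lower in the knockdown array. With 1 array per group these differences had no replicate check and no p-values, and they describe 2 arrays. RAP1A, a Ras-like GTPase and a member of the neurotrophin list, gave the largest difference, 4.34, on 1 of its 4 probe sets, whereas the other 3 differed by 0.04 to 0.06. In the control array that probe set read 6.54, below the other 3 at 8.35 to 8.46. It had the highest mean, and so stood for the gene, only through its level of 10.88 in the knockdown array. After USF1 knockdown that probe set rose by 2.48 (SE 0.05, adjusted p = 4.11e-05) and the others differed by -0.01 to 0.09. MMP1 was higher by 2.67, on a level of 5.17 in the control, ARL14 by 1.71, SYCE3 by 1.39 and EGR1 by 1.37, where the bright EGR1 probe sets ran from 0.51 to 1.53. The lysosomal protease CTSZ, IFNE and AGBL2 lay under the dim limit of 4.76 in the control, at 4.64, 4.09 and 4.18. They were higher by 1.82, 1.51 and 1.46 as measured, by 1.71, 0.85 and 0.88 counted from the limit, and by 1.35, 0.97 and 0.95 with 16 intensity units added. The mitochondrial peroxidase PRDX3 was lower (-1.77), as were the endosomal GTPase RAB5C (-1.29), the replicative helicase subunit MCM2 (-1.21), FAM217B (-1.13), ANKRD46 (-1.13) and the integrin subunit ITGB5 (-1.08). The bright probe sets of FAM217B ran from -1.13 to -0.38 and those of ANKRD46 from -1.13 to -0.30, and the means of all their probe sets gave -0.76 and -0.71. PURB and ASPH were lower on their brightest probe sets (-1.43 and -1.40) but not on all, and with the mean of all probe sets the differences were -0.45 and -0.36. At the planned limit of 2-fold this pair had 31 genes, against 0 in each of the 6 pairs of USF1 replicate arrays. At 1.5-fold, a limit not planned for this count, 414 of 11620 genes differed in this pair, against 0 to 17 of 11448 within the 6 replicate pairs. The 2 gene sets were kept above unlike limits, 4.76 and 5.63. The USF1 replicates may be technical, so their counts do not measure the spread between separate cultures.

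Genes of G1/S and DNA replication were lower in the UGT1A3 knockdown array in 33 of 34 cases, with MCM2 at -1.21 and MCM10 at -0.96. Their median of -0.56 lay below all 10000 random lists matched on expression. All 34 G2/M genes were lower, with CDC20 at -0.62 (-0.72 to -0.18 over its bright probe sets) and CCNA2 at -0.49 and a median of -0.21 (percentile 0.01). Replication-dependent histones were higher in 10 of 12 cases, with H2BC4 at 1.08, H2BC5 at 0.90 and a median of 0.49 (percentile 100). Interferon genes had a median of 0.26 (percentile 99.9, 16 of 20 higher), with ISG20 at 1.21 and IFIT2 at 1.11. Lysosomal genes (0.15, percentile 99.8) included WIPI1 at 0.65, and p53 targets (0.20, percentile 99.6) included SESN2 at 0.77 and TP53INP1 at 0.98, or 0.37 with the mean of all its probe sets. NRF2 and xenobiotic genes had a median of 0.15 (percentile 98.9, ABCC2 at 0.69, or 0.35 with the mean of all its probe sets), immediate early and ERK feedback genes 0.12 (percentile 98.3, DUSP6 at 0.82) and TGF-beta targets 0.16 (percentile 98.2, TGFBR2 at 0.32 and 0.71 on its 2 bright probe sets). Heat shock genes had a median of -0.15 (percentile 0.79, 5 of 15 higher), with DNAJB1 at -0.29 and DNAJB4 at 0.39. Glycolysis and hypoxia genes had one of -0.10 (percentile 0.84, 9 of 28 higher), with ADM at -0.55 and BNIP3L at 0.45. These percentiles are a description of these 2 arrays. The lysosomal, p53, NRF2, immediate early and TGF-beta lists came back inside the central 95% of random lists under at least 1 other setting.

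The other 14 lists lay inside the central 95% of random lists, though with the mean of all probe sets reported USF targets (-0.16, percentile 1.39) and neuronal markers (0.22, percentile 97.7) lay outside it. Neurotrophin genes had a median of 0.01 (percentile 39.4), with 42 of 76 higher, 33 lower, JUN at 0.71 and RAP1A at 4.34. Reported USF targets had a median of -0.11 (percentile 3.44), with ABCA1 at 0.68 and APOE at 0.56, and E-box factors one of 0.03 (percentile 49.6), with BHLHE41 at 0.69 (0.45 with the mean of all its probe sets). Apoptosis regulators (0.10, percentile 94.3, 18 of 30 higher) included CASP2 at -0.76 and BBC3 at 0.67 (mean of all its probe sets 0.32). Cholesterol synthesis genes (-0.06, percentile 9.47) included TM7SF2 at 0.57 (0.24 to 0.57 over its bright probe sets). Fatty acid synthesis genes (0.04, percentile 63.4, 12 of 23 higher) included FASN at -0.52 and ACACB at 0.46 (mean of all its probe sets 0.19). Oxidative phosphorylation genes had a median of 0.02 (percentile 66.1), ribosomal proteins of 0.05 (percentile 92.4), and unfolded protein response and ATF4 targets of -0.01 (percentile 28.7), with SLC7A5 at -0.61 and -0.37 on its 2 bright probe sets. The medians were 0.10 for NF-kB genes (percentile 81.7), -0.03 for epithelial genes (percentile 25), 0.05 for mesenchymal genes (percentile 73.6, MMP14 at 0.88), -0.10 for alveolar markers (percentile 15) and 0.08 for neuronal markers (percentile 67.9, CHGB at 0.59 to 1.17 over its bright probe sets). Median and mean differed in sign for cholesterol synthesis (mean 0.01), fatty acid synthesis (mean -0.03) and unfolded protein response genes (mean 0.04). Of the markers too few to be set among random lists, PDGFRB differed by -0.12, CD68 by 0.47 (0.29 on its second bright probe set), CD3E by -0.28 (4.74 in the knockdown array, under the dim limit), PECAM1 by -0.10, VWF by 0.17, UGT8 by -0.06 and UGT3A1 by -0.37. The 12 poly-A spike-in probe sets were all higher in the UGT1A3 knockdown array, by a median of 0.49, and the 9 hybridization spike-in probe sets had a median difference of 0.19. After USF1 knockdown these medians were 0.16 and 0.06.

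Across the 11130 genes measured in both sets, the 2484 that rose after USF1 knockdown had a median difference of 0.12 in the UGT1A3 pair, and the 2112 that fell had one of -0.01. Expression-matched random lists had a median of 0.02, and the observed medians lay above and below all 2000 of them. Pearson's correlation of the 2 sets of log2 values across genes was 0.17 and Spearman's 0.18, where genes are not independent replicates. The sets share no control arrays. BFSP1 (1.44 and 1.01), H2BC4 (0.39 and 1.08), GSAP (0.30 and 1.23, or 0.17 and 0.87 on its second bright probe set), ARL14 (0.29 and 1.71) and CTSZ rose after USF1 knockdown and were at least 2-fold higher in the UGT1A3 knockdown array. The controls of CTSZ lay under the dim limit in both sets, and counted from the limits it was higher by 0.38 and 1.71. PRDX3 (-0.27 and -1.77), SPG21 (-0.17 and -1.06), CDC42SE2 (-0.16 and -1.03), SLC5A6 (-0.13 and -1.06) and ASPH (-0.09 and -1.40) fell and were at least 2-fold lower. Independent lists would share 3.79 genes upward and 2.09 downward, and 4 genes that rose were at least 2-fold lower and 5 that fell at least 2-fold higher. The count of 10 genes moving the same way was 6 without USF1 control 1, 2 or 3 or USF1 knockdown 1 or 3, and 8 without USF1 knockdown 2. CTSZ, GSAP, CDC42SE2, SLC5A6 and ASPH each lost their call without at least 1 of these arrays, and the 3 bright probe sets of CDC42SE2 ran from -0.16 to 0.03 after USF1 knockdown.

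**Figure D3:**
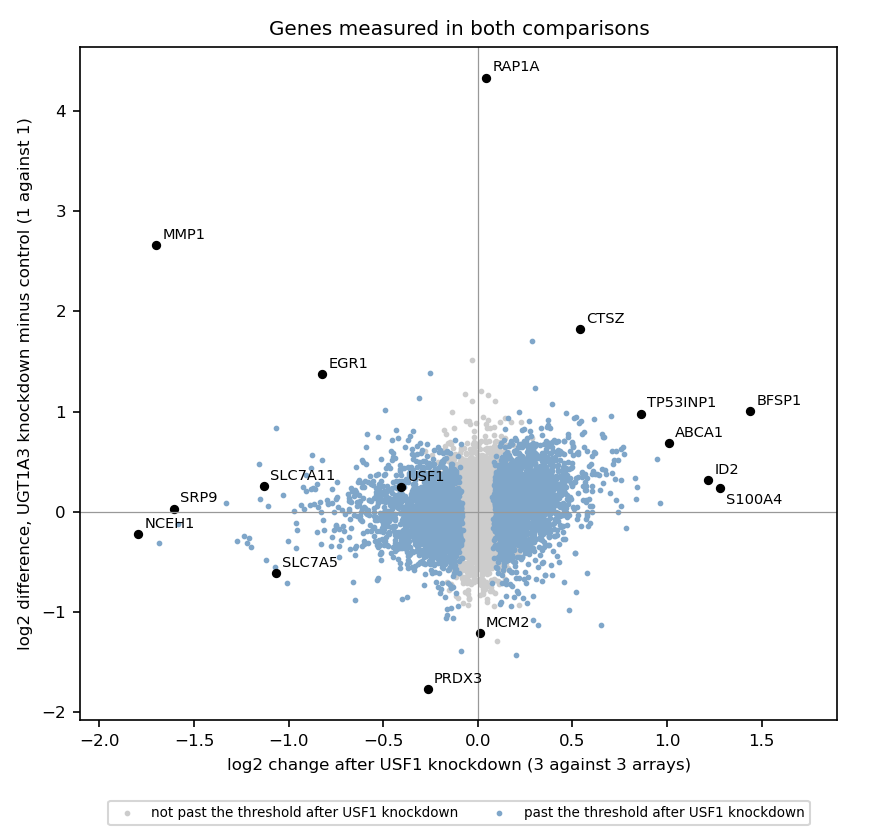
Log2 change after USF1 knockdown (horizontal axis, mean of 3 arrays minus mean of 3 controls) against the log2 difference between the UGT1A3 knockdown array and its control (vertical axis, 1 against 1 array) for each of 11130 genes, with genes past the adjusted p threshold after USF1 knockdown in blue, the others in grey and named genes in black. MMP1 and EGR1 lie low on the horizontal and high on the vertical axis, at -1.70 and 2.67 and at -0.82 and 1.37. RAP1A is drawn at its brightest probe set of each set of arrays, which was not the same one in both. The probe set behind its vertical value of 4.34 rose by 2.48 after USF1 knockdown.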

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

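The limits that picked out the genes below (1.5-fold in both sets, and a 4-fold gap between probe sets), the test of RNA quality and the 3 tests on RAP1A were chosen only after the results were seen. No group had 4 or more arrays, so single arrays were not tested for standing apart.

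Genes that passed after USF1 knockdown with at least a 1.5-fold change, and that differed at least 1.5-fold the other way in the UGT1A3 pair, were picked out as opposite between the knockdowns. The difference between the knockdowns was not tested, since the UGT1A3 pair has 1 array per group. The collagenase gene MMP1 had a log2 change of -1.698 after USF1 knockdown and a difference of 2.67 in the UGT1A3 pair. Its control level was 10.45 in the USF1 set and 5.17 in the UGT1A3 set. The control levels of INSIG1 were 12.38 and 7.54, but those of SRP9 were 11.41 and 11.03. The controls of the sets thus differed by more than a shared shift in level. Opposite values may reflect the set as well as the gene targeted, and these were not separated. SMIM14 had values of -1.064 and 0.84. The immediate early gene EGR1 had values of -0.8235 and 1.37. ANKRD46 had values of 0.6522 and -1.13, and its second bright probe set had a change of -0.02 after USF1 knockdown. The zinc finger gene ZNF267 had values of -0.5925 and 0.65, and the stress-induced gene SESN2 had values of -0.5853 and 0.77. By chance 2.76 genes would have fallen after USF1 knockdown and been higher in the UGT1A3 pair, against 5 observed, and 0.81 the reverse, against 1 observed.

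A RAP1A probe set that the gene-level test of the USF1 comparison did not use rose by 2.476 on the log2 scale after USF1 knockdown, and by 4.34 in the UGT1A3 pair. A rise of all RAP1A transcripts is argued against by the other 3 RAP1A probe sets, whose median change was at most 0.04523 in either set. A defect of 1 array is argued against because the lowest of the 4 knockdown arrays still lay 2.451 above its control mean. A sequence other than RAP1A binding this probe set, for example one carried by the knockdown constructs, stays open together with a rise of a single RAP1A transcript. All 3 other probe sets changed by less than 1.5-fold in both sets, but probe and construct sequences were not compared here, so these 2 cannot be told apart.

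USF1 fell to 75.6% of its control level while 4657 of 11448 genes passed the threshold. Under quantile normalization and median centring the lower of the 2 counts was 102.7% of that number, which argues against a leftover difference in scale between the deposited arrays. The medians of the 6 arrays already lay between 6.53 and 6.55, so neither step could show an effect of the authors' own scaling, which stays open. RNA quality is argued against by a shift of -0.006663 in the difference between 3' and 5' control probe sets, with a within-group SD of 0.01. Probe background hiding a larger fall of USF1 stays open: after subtraction of each array's 40th percentile the knockdown level was 42.07% of control, with an SD of 13.3 over the 3 arrays, and a background set at that percentile is itself an assumption. An effect of the USF1 knockdown on other genes stays open as well and was not separated from effects of the hairpin on other targets. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 4657 genes and the highest of the others gave 0. Each of the others mixes the 2 groups, which puts any group difference into the spread within groups. Their low counts therefore add nothing to the fit itself.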

How the results depend on the processing

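The list of neurotrophin genes without RAP1A was the 1 alternative chosen only after the result was seen. The genes that passed after USF1 knockdown numbered 3644 to 5364 over the gene-level alternatives, with 51.8% to 56.8% rising, and 3451 of the 3644 called without a dim limit were among the original 4657. With every probe set tested on its own, 11030 of 29576 passed, a larger number of tests by construction. Leaving out 1 USF1 array gave 3644 to 4365 genes, 4 to 6 lists and a USF1 change of -0.46 to -0.33. With the dim limit at the 60th percentile USF1 kept its change of -0.4035 but lay under the limit and was not tested, 2 lists passed in place of 5, and 6 genes in place of 10 passed and were 2-fold the same way in both sets; fewer genes were tested there. With 16 intensity units added that number was also 6, and 18 genes in place of 31 were 2-fold different in the UGT1A3 pair, since the addition shrinks differences of dim genes. Leaving out 1 USF1 array gave 6 to 8 such shared genes. Among named genes and lists, 52 gene values and 6 list values lost their call after USF1 knockdown, 3 and 4 gained one, and 1617 and 338 stayed as they were, passed or not. In the UGT1A3 pair 54 gene values moved by more than the replicate spread of the USF1 arrays, 361 did not, and UGT8 changed sign from -0.06 to 0.0293 with the mean of all probe sets. Of the list medians there 7 came inside the central range of random lists, 2 left it and 139 kept their side. The cause was not tested where none is named. With the replicate number as a block 4233 genes passed, 4013 of them among the original ones. Whether the numbers pair the arrays stays undecided. Deviations from the group means correlated at -0.10, 0.20 and 0.09 for numbers 1, 2 and 3. Of the 6 arrays 3 correlated best with their own number. The UGT1A genes lay under the dim limit in both sets, so signal over background limits any statement on them.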

Other observations

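The genes named in the next paragraph and the tests of a smaller amount of RNA and of a difference between single cultures were chosen only after the results were seen.

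At a limit of 1.5-fold in both sets, 15 genes rose after USF1 knockdown and were higher in the UGT1A3 knockdown array, where independent lists would share 1.15, and 4 fell and were lower, where independent lists would share 1.95. Among the former were ABCA1, which exports cholesterol (1.01 and 0.68), MAP2, a microtubule-associated protein of neurons (0.86 and 0.96, or 0.92 counted from the dim limit, which its UGT1A3 control of 4.72 lay under), and the stress-responsive TP53INP1 (0.86 and 0.98), which with the mean of all its probe sets had 0.46 and 0.37, under the limit in both sets. The matrix genes FBN1 (0.73 and 0.60), OLFML2A (0.66 and 0.75) and TGFBI (0.62 and 0.59) belonged there too, as did TET1, which oxidises methylated cytosine (0.76 and 0.65), and the stress kinase MAPK10 (0.76 and 0.63). The 4 lower genes were RCC2 (-1.01 and -0.71), ZNF826P (-0.66 and -0.70), the tumour suppressor NF2 (-0.65 and -0.88) and the amino acid transporter SLC7A5 (-1.07 and -0.61, or -0.75 and -0.49 with the mean of all its probe sets). The second value of each pair comes from 1 array against 1.

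Replication genes were lower in the UGT1A3 knockdown array (G1/S median -0.56) while their median after USF1 knockdown was 0.01, and the difference between the sets was not tested. The median nearer 0 after quantile normalization or median centring was -0.5432 and still lay below the random lists, which argues against a leftover difference in scale between the 2 deposited arrays. Their medians were already close, at 5.59 and 5.63, so these steps could move a list only little and do not test the authors' own scaling. A smaller amount of sample RNA, which the higher poly-A spike-ins (0.49) might reflect, was taken to shift genes of the same brightness alike. The median of -0.5559, against 0.02 for random lists of the same brightness, argues against such a shift as the whole source. Both values were already known when this test was chosen. A difference between single cultures that is not due to the knockdown, such as in cell density, cannot be told apart from an effect of the UGT1A3 knockdown with 1 pair of arrays.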
